A study of Drosophila melanogaster with 2 samples.

How the data were processed

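Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done with an antibody against GFP in whole adult Drosophila melanogaster of both sexes. Per the labels, the flies came from a transgenic line that stably expresses the protein of the homeobox gene CG11617 with GFP at its C terminus. The series holds 1 group with 2 biological replicates, which the labels number 2 and 3. Chromatin was fragmented by sonication, per the labels. The labels name a matched control experiment and the deposited notes name a control alignment among the inputs of the peak lists; no control sample was analysed here.

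The authors deposited peak lists in the narrowPeak layout on the dm6 and dm3 genome builds, per the notes deposited with them. For each build there is a list of candidate peaks with background for each replicate, a list of the same kind for the pooled replicates, and an optimal set after the authors' filter on the irreproducible discovery rate (IDR), a measure of how well peak ranks agree between replicates. Each list of candidates holds 30000 entries. The deposited signal value of each entry is the authors' peak score, and it was used here to describe, rank and filter entries within a list. Signals are not scaled between lists, and the median signal was 24.0 in replicate 2 and 46.5 in replicate 3. The deposited −log10 q values were capped at a single highest value in each list, which 45.1% of the replicate 2 entries, 54.6% of the replicate 3 entries and 54.5% of the pooled entries shared, so they were not used for ranking. The aligner, the peak caller and their versions are not given in the sources used here. The lists give no read counts, so the depth of each library is unknown, and no interval that needs a read count is given.

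Coordinates are dm6, counted from 1. The dm6 entries were compared with the Release 6 genome sequence, whose 6 arms 2L, 2R, 3L, 3R, 4 and X hold every dm6 entry within their lengths, and with the protein-coding gene models of Ensembl release 115 (BDGP 6.54). No entry lay on the Y chromosome in any list, so Y was left out of the tests and of the gene universe, a departure from the plan. The gene universe was 13945 protein-coding genes with 19607 distinct transcription start sites (TSSs). No coordinate was converted between builds, and the dm3 lists were used for counts and overlaps among themselves.

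Each IDR summit was put in the first class that applied among promoter (within 500 bp of a protein-coding TSS), 5' UTR, 3' UTR, coding exon, intron and intergenic. Class shares were compared with 1000 circular shifts of all summits within their arms (permutation test, two-sided), whose smallest possible p is 0.001998. The share of replicate 2's highest-signal entries that overlapped replicate 3's by at least 1 bp was compared with 1000 circular shifts (permutation test, one-sided; smallest possible p 0.000999). The number of entries per arm was tested with an exact binomial test on arm length. Gene lists were tested with a two-sided Fisher's exact test of members against all other protein-coding genes. Motifs were searched on both strands in windows of 101 bp centred on each summit and in windows of the same length centred 350 bp to a randomly chosen side, with an exact McNemar test. Median log2 signal of promoter and other entries was compared by a permutation test with 100000 resamples. P-values were adjusted by the Benjamini-Hochberg method within each family with a threshold of 0.05, and shares carry 95% Wilson intervals. Peaks and genes are not independent replicates, and neighbouring peaks can share a cause, so these tests describe these peak lists, and their p-values and intervals cover counting error only. With 2 replicates in 1 group there is no test between samples.

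The 21 gene lists, the 17 motifs, the tests and the alternatives were fixed before the data were examined, together with the rule for named genes. Named are the 20 IDR peaks of highest signal after overlapping entries were merged, each with the protein-coding gene of nearest TSS, the tagged gene CG11617, up to 4 members of each list with the highest IDR signal within 500 bp of a TSS, list members without a peak when fewer than 6, and the 5 6-mers of highest enrichment. A gene that this rule selects is not reported here. A further 11 gene lists and 6 alternatives were written after the data were seen. Symbols of 7 planned list members did not match the annotation and were left out. Alternatives changed the promoter window, the overlap rule, the peak set, the genome build, the motif window and the background, and left out each replicate by taking the other replicate's 5777 highest-signal entries. Added alternatives stratified the list tests by number of TSSs or by gene length (Mantel-Haenszel), merged overlapping entries for motifs and 6-mers, kept only promoter summits, or replaced flanks by summit sequences shuffled to keep dinucleotide counts.

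The tests were tried on simulated data. For the gene list comparison over 13945 genes, 8 of 10 lists of 60 genes with 3 times the odds of a peak were called, and 0 of 200 unchanged lists. For the 6-mer comparison, 20 of 20 6-mers planted in 5% of summit windows were called, with 42 of the other 2060, and 6 of the 1795 that shared no run of 5 bases with a planted one. Simulated summit and flank windows had the same base composition, whereas the real ones held 36.9% and 43.2% GC. These counts therefore do not cover calls that follow from composition. For the promoter share, 4 of 100 sets of 1000 uniformly placed summits passed the threshold. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.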

Results

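Binding of a GFP-tagged form of CG11617, a homeobox protein, was mapped by ChIP-seq with an anti-GFP antibody in whole adult flies of both sexes. The data comprised 2 biological replicates of 1 group, numbered 2 and 3, and the authors' optimal set of peaks after their IDR filter. That set held 5777 entries on dm6, which joined into 4874 separate regions covering 2.22 Mb, or 1.66% of the 6 chromosome arms. The authors' signal in the pooled list ran from 163 to 5197 over these entries with a median of 263. All 5777 were the highest-signal entries of the pooled list of 30000. Read depth was unknown because the lists carry no counts.

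The 2 replicates recovered largely the same regions. Of the 5777 highest-signal entries of replicate 2, 5041 (87.3%) overlapped 1 of the 5777 highest of replicate 3, against 3.34% ± 0.32 (SD) in 1000 circular shifts (one-sided permutation p = 0.000999, the smallest possible). Counted from replicate 3, the overlap was 82.2%. The remaining values are over IDR entries, which the authors' filter chose for agreement between the same 2 replicates. They describe that agreement and do not test it. All but 4 IDR entries overlapped an entry of the full replicate 2 list, and all but 13 an entry of the replicate 3 list. Across the 5760 entries found in both, signal had a Spearman rho of 0.839, a correlation across peaks, which are not independent replicates. Replicate 3 signal was a median 2.21-fold above replicate 2, a log2 ratio of 1.14, where signals were not scaled between lists. Once that shift was removed, the ratio had an SD of 0.42 on the log2 scale, and 154 entries (2.67%) departed from it by more than 2-fold. Pooled signal was near the sum of the 2 replicate signals at the strongest peak (5197, with 1546 and 3650), so replicate 3 weighed more in it. Of the IDR entries, 5502 overlapped 1 of the 5777 highest of replicate 3, and 5061 overlapped 1 of the 5777 highest of replicate 2.

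The strongest peaks lay at or near genes of varied function. The highest of all, with a pooled signal of 5197, was in an intron of the uncharacterised gene CG11050 at 2L 6612252 to 6613233, 1024 bp downstream of its nearest TSS, and ranked 1 in both replicates (signal 1546 in replicate 2 and 3650 in replicate 3). The next was at the promoter of Gapdh2, which encodes the glycolytic enzyme glyceraldehyde-3-phosphate dehydrogenase (X 15867603 to 15868434; pooled signal 3440, 1049 in replicate 2 and 2397 in replicate 3), and ranked 2 in both replicates. Hexokinase A, the enzyme that starts glycolysis, also had a promoter peak in this group (Hex-A, X 9584402 to 9585934, pooled signal 2861). Peaks at regulators of chromatin and transcription included those in the intron of Trl, which encodes GAGA factor (2601), near the HMG-box genes HmgZ (3006) and bbx (2327), near the zinc-finger gene cbt (2499, within an intron of ush), and in the intron of Tlk, the Tousled-like kinase (2560). The kinase genes Lk6 (3057) and gish (2345), the nucleotide-sugar transporter gene Ugalt (2715) and the ER-associated degradation gene Hrd3 (2362) were also among the 20 strongest. The other 8 of the 20 strongest peaks had as nearest genes CG14100 (3025), CG4004 (2838), CG32772 (2819), CG18428 (2713), CG16753 (2610), CG31145 (2562), CG11309 (2482) and CG12769 (2371). Of the 20, 10 summits were in promoters, 9 in introns and 1 in intergenic sequence, 5020 bp from the nearest TSS, that of CG4004. Each of the 20 ranked no lower than 24 in either replicate, and their replicate ratios lay within 0.22 of the common shift on the log2 scale.

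Most binding was at promoters. Of the 5777 summits, 3841 (66.5%, 95% interval 65.3 to 67.7%) lay within 500 bp of a protein-coding TSS, 5.79 times the 11.5% ± 0.63 (SD) of shifted summits (two-sided permutation, adjusted p = 0.0024, from the smallest p possible). Coding exons held 10 summits (0.17% against 13.3% in shifted sets), 3' UTRs 60 (1.04% against 5.17%), introns 1435 (24.8% against 39.4%) and intergenic sequence 383 (6.63% against 29.9%), and each of these 4 classes was lower with the same adjusted p. Each summit has only 1 class, so the high promoter share itself lowers the other shares, and these 4 results are not independent. Outside promoters, 1435 of 1936 summits were in introns. In shifted sets introns held 39.4% of all summits and promoters 11.5%, so outside promoters the intron share was higher than after shifting. The lower intron share among all summits therefore does not show that introns were avoided. The comparison outside promoters was not tested. The 48 summits in 5' UTRs (0.83%) did not pass against the shifted 0.80% (permutation, adjusted p = 0.83). Among pooled entries that did not pass the IDR filter, 36.8% were promoter summits. A total of 999 summits (17.3%) lay more than 2 kb from any TSS.

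**Figure D1:**
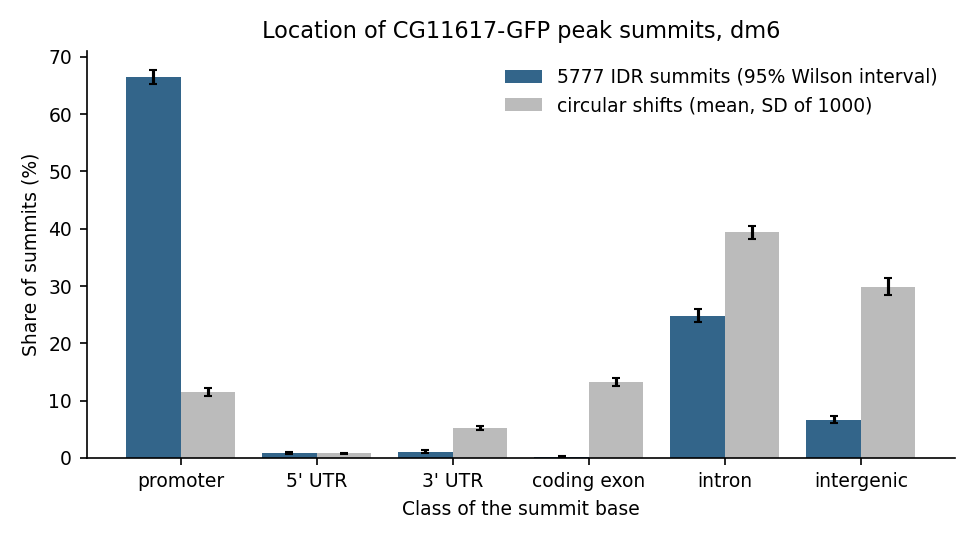
Share of the 5777 IDR summits (blue, 95% Wilson interval) and of circularly shifted summits (grey, mean and SD of 1000 shifts) in each class of the dm6 annotation, in percent. Promoters held 66.5% of summits against 11.5% after shifting, and coding exons 0.17% against 13.3%.

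Within promoters the summits sat just upstream of the start site. The median position was -65 bp, with quartiles at -160 and 30 bp, and 2658 of the 3841 summits (69.2%, 67.7 to 70.6%) were upstream of the nearest TSS. TSSs of both strands lay within the promoter window for 1426 summits (37.1%), so for these the gene bound cannot be read from position alone. Promoter entries had a median signal of 269 and other entries 250, a difference of 0.11 on the log2 scale (two-sided permutation test, 100000 resamples, p = 2.0e-05). When entries were ranked by signal and split into 10 equal groups, the promoter share was 64.7% in the lowest group and 73.4% in the highest.

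**Figure D2:**
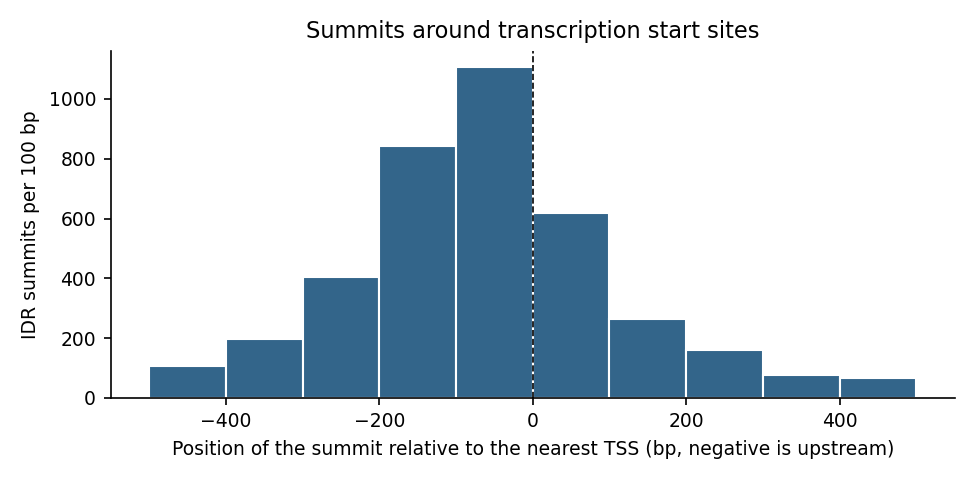
Number of IDR summits per 100 bp by position relative to the nearest protein-coding TSS, for the 3841 promoter summits. The tallest bin, with 1106 summits, is the 100 bp immediately upstream of the TSS, and the next, with 843, lies upstream of it.

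Genes of the translation machinery carried promoter peaks far more often than other genes. In all, 4178 of 13945 protein-coding genes (30.0%, 29.2 to 30.7%) had an IDR summit within 500 bp of a TSS. Among genes for cytosolic ribosomal proteins this was 77 of 86 (89.5%; odds ratio 20.4, 10.2 to 46.2; Fisher's exact test, adjusted p = 1.3e-29), with a median signal of 635. Among the strongest were RpS27 (pooled signal 1598, 474 in replicate 2 and 1110 in replicate 3), RpS10b (1450, 451 and 1000) and RpL28 (1442, 445 and 975). Mitochondrial ribosomal protein genes had a peak in 46 of 73 cases (63.0%; odds ratio 4.02, 2.44 to 6.73; exact adjusted p = 3.1e-08), led by mRpS10 (1854), mRpL41 (1698), mRpL23 (1483) and mRpS23 (1355). Translation factor genes did so in 26 of 54 cases (48.1%; odds ratio 2.18, 1.23 to 3.86; exact adjusted p = 0.014), led by eIF4EHP (2713), eIF6 (1675), eIF1 (1442) and eEF1gamma (1174). The eIF1 peak is also the RpL28 peak, since the 2 genes share a divergent promoter, and the eIF4EHP peak is shared with CG18428. When only the 8588 genes with any pooled entry at a TSS were compared, the odds ratio of mitochondrial ribosomal protein genes was 2.03 (exact adjusted p = 0.027) and translation factors no longer passed (1.62, exact adjusted p = 0.21). Stratified by gene length, the odds ratio was 47.8 for cytosolic and 7.39 for mitochondrial ribosomal protein genes.

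Core clock genes were also bound more often. Of 8 circadian clock genes, 6 had a promoter peak (odds ratio 7.02, 1.25 to 71.2; exact adjusted p = 0.021). The photoreceptor gene cry had the highest signal (1823, 615 in replicate 2 and 1224 in replicate 3; 3R 19211612 to 19212254), followed by the leucine-zipper regulator gene Pdp1 (1004), and by tim (963) and per (458), whose products form the repressor of the clock. Clk and cwo had none. This call rests on few genes and did not pass with a promoter window of 250 bp (odds ratio 4.89, exact adjusted p = 0.051), after stratification by gene length (4.71, Mantel-Haenszel adjusted p = 0.055) or among genes with a pooled entry (odds ratio 3.17, exact adjusted p = 0.25). The excess was larger with replicate 2 alone (7 of 8, odds ratio 17.96, exact adjusted p = 0.0019) and among the 50% of entries with highest signal (13.8, exact adjusted p = 0.0020).

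**Figure D3:**
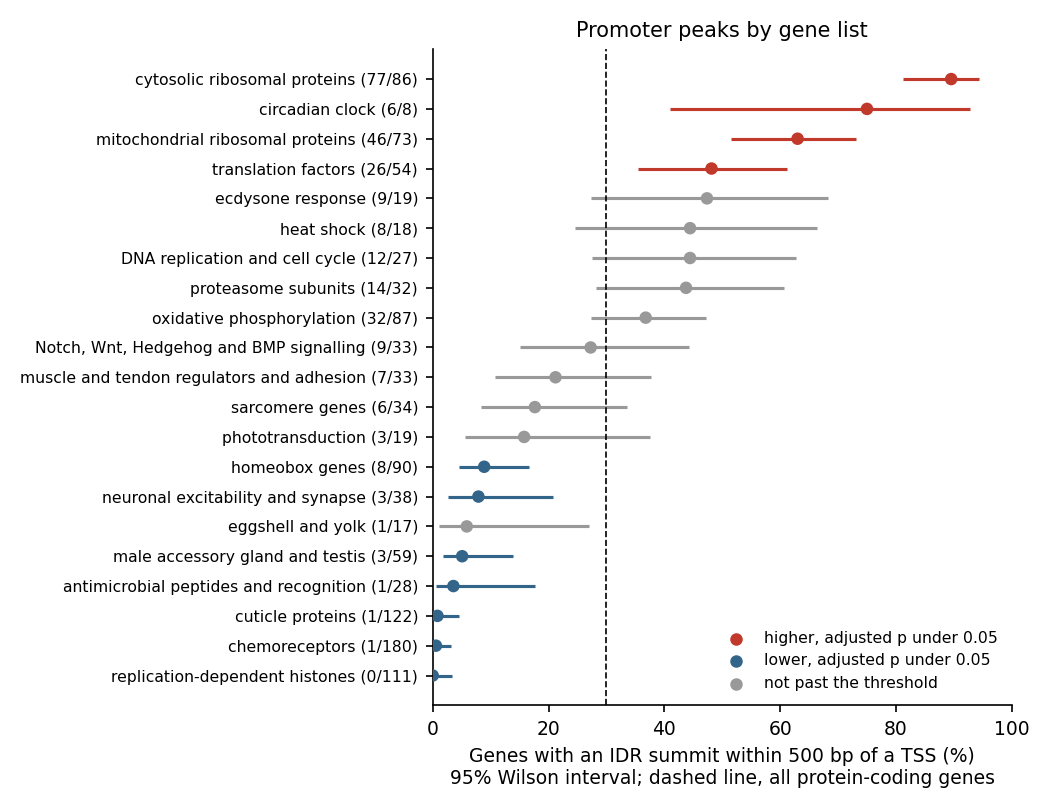
Percent of genes in each of 21 lists with an IDR summit within 500 bp of a TSS (points) with the 95% Wilson interval (lines), where red and blue lists were higher and lower than other genes at an adjusted p under 0.05 and grey lists were not past it. Cytosolic ribosomal protein genes were highest with 77 of 86, and the dashed line marks the 30.0% of all protein-coding genes.

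Several lists of genes with tissue-restricted roles carried peaks less often than other genes. The chromatin came from whole adults, so binding confined to few cells could fall below the IDR filter, and this was not tested. Homeobox genes had a peak in 8 of 90 cases (8.89%; odds ratio 0.23, 0.095 to 0.47; exact adjusted p = 8.1e-06), with the highest signals at tin (357), NK7.1 (344), CG11617 itself (330) and Six4 (236). Chemoreceptor genes had 1 of 180 (Gr63a, 166; odds ratio 0.013, exact adjusted p = 1.0e-25) and cuticle protein genes 1 of 122 (Cpr73D, 194; odds ratio 0.019, exact adjusted p = 4.9e-17). Genes of the male accessory gland and testis had 3 of 59 (Mst36Fa, 474; Mst85C, 383; Sfp26Ad, 326; odds ratio 0.12, exact adjusted p = 8.5e-06), and each of these summits lay inside a neighbouring gene. Genes of neuronal excitability and the synapse had 3 of 38 (elav, 1411; comt, 289; Syx1A, 218; odds ratio 0.20, exact adjusted p = 0.0048), where the comt peak is also the mew peak of the muscle list and the elav summit lies inside the neighbouring gene arg. Antimicrobial peptide and recognition genes had 1 of 28 (PGRP-LB, 397; odds ratio 0.086, exact adjusted p = 0.0034). The neuronal and antimicrobial lists did not pass among the 50% of entries with highest signal (odds ratios 0.25 and 0.17, exact adjusted p = 0.091 and 0.090), and the antimicrobial list did not after stratification by gene length (0.16, Mantel-Haenszel adjusted p = 0.11). Few chemoreceptor (10), cuticle (8), male (7) and antimicrobial (10) genes had any pooled entry at a TSS, and among genes with such an entry these 4 lists did not pass (odds ratios 0.12, 0.15, 0.79 and 0.12; exact adjusted p = 0.055, 0.16, 1 and 0.055). Homeobox genes (8 of 55, odds ratio 0.18, exact adjusted p = 1.8e-06) and neuronal genes (3 of 25, 0.14, exact adjusted p = 0.0012) stayed lower in that comparison. With replicate 3 alone no chemoreceptor gene had a peak (0 of 180). With a promoter window of 250 bp no chemoreceptor, cuticle, male or antimicrobial gene had a peak, and with 1000 bp the odds ratio was 0.046 for chemoreceptor and 0.034 for cuticle genes. It was 0.24 for male genes both among the 50% of entries with highest signal and stratified by gene length, and 0.13 for neuronal genes stratified by gene length. The replication-dependent histone genes had 0 of 111 with a peak and 0 with a pooled entry. They lie in many near-identical copies, which can share reads. The lists do not show how such reads were placed, so the absence is uncertain.

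Other lists did not differ from the remaining genes at this threshold. Proteasome subunits had 14 of 32 with a peak (odds ratio 1.82, 0.84 to 3.88; led by Rpn5, Rpn3, Rpn13 and Rpn11) and oxidative phosphorylation 32 of 87 (1.36, 0.85 to 2.15; led by ND-42, SdhC, ND-ASHI and ND-SGDH). Both had odds ratios above 1, and proteasome genes passed with replicate 3 alone (odds ratio 2.30, exact adjusted p = 0.035) while oxidative phosphorylation passed with replicate 2 alone (1.73, exact adjusted p = 0.026). Stratified by gene length both passed (odds ratios 2.36 and 1.99, Mantel-Haenszel adjusted p = 0.035 and 0.0035), whereas among genes with a pooled entry they stood at 0.87 and 0.99 (exact adjusted p = 0.85 and 1). Ecdysone response genes had 9 of 19 (Eip75B, E23, usp and EcR), heat shock genes 8 of 18 (Hsp83, Hsp27, Hsp26 and stv), and replication and cell cycle genes 12 of 27 (RnrS, CycE, dpa and Mcm2). Notch, Wnt, Hedgehog and BMP signalling genes had 9 of 33 (shn, tkv, arr and H). Muscle and tendon regulators had 7 of 33 (tin, Mef2, mew and sd), sarcomere genes 6 of 34 (Msp300, flr, Tm1 and Zasp52), phototransduction genes 3 of 19 (rdgB, rdgC and norpA), and eggshell and yolk genes 1 of 17 (Yp3, adjusted p = 0.056 by an exact test). Of the 10 heat shock genes without a peak, 6 are Hsp70 copies, which are near identical and carry the same limit as the histone genes, and among genes with a pooled entry the list had 8 of 9 (odds ratio 8.46 against 1.87, exact adjusted p = 0.055). In that comparison phototransduction genes had 3 of 5 (1.58 against 0.44, exact adjusted p = 0.85) and replication and cell cycle genes 12 of 26 (0.90 against 1.87, exact adjusted p = 0.94). Sarcomere genes were lower past the threshold with replicate 2 alone (odds ratio 0.25, exact adjusted p = 0.020), among the 50% of entries with highest signal (0.14, exact adjusted p = 0.046), and stratified by number of TSSs (0.23, Mantel-Haenszel adjusted p = 0.0034) or by gene length (0.35, Mantel-Haenszel adjusted p = 0.033). Eggshell and yolk genes were lower with promoter windows of 250 bp (exact adjusted p = 0.020) and 1000 bp (0.032).

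Sequence at the summits was rich in A and T and held binding motifs of known promoter factors. The GC content was 36.9% in the 101 bp around summits and 43.2% in flanks. Of 17 motifs, 9 were more frequent at summits than in flanks and 2 less. The largest ratios were those of TATCGATA, the site of DREF (142 against 38 of 5777 windows, 3.74-fold, McNemar exact adjusted p = 4.7e-15), of the CTCF-type AGRKGGCGC (28 against 8, 3.50-fold, adjusted p = 0.0023) and of GGTCACACT, the site of M1BP (70 against 22, 3.18-fold, adjusted p = 1.5e-06). The M1BP site occurred at 70 of 3841 promoter summits and 0 of 1936 others, and the DREF site at 134 (3.49%) and 8 (0.41%). The homeodomain core TAATTA was at 9.61% of summits and 5.63% of flanks (1.71-fold, exact adjusted p = 1.4e-15), and TAACA, a core of Iroquois-type homeodomains, at 24.8% and 17.4% (1.42-fold, adjusted p = 4.3e-21). TATAAA (1.81-fold), CGATA, part of the BEAF-32 site (1.40-fold), the A tract (1.38-fold) and the GATA site WGATAA (1.25-fold) were also higher. The palindrome ACATGT was found in 137 summit and 137 flank windows (exact adjusted p = 1), and TGACAG in 178 and 166 (adjusted p = 0.62). At promoter summits alone TGACAG was higher (1.5-fold, exact adjusted p = 0.0058), and it was more frequent there than at other summits (odds ratio 1.60, Fisher's exact adjusted p = 0.022). CGATA was also more frequent at promoter than at other summits (odds ratio 2.00, Fisher's exact adjusted p = 1.9e-18), and WGATAA (0.73, adjusted p = 9.9e-05), the A tract (0.73, adjusted p = 0.0079) and TGASTCA (0.52, adjusted p = 0.039) were less frequent there. CACGTG (0.70-fold, exact adjusted p = 0.034) and CACACACA (0.76-fold, adjusted p = 0.016) were lower. The other 4 motifs (GAGAGAG, CAGGTAG, TCAGTY and TGASTCA) did not pass. Several of these calls depended on the setting. With replicate 2 alone the CTCF-type motif (1.06-fold, exact adjusted p = 1) and CACGTG (0.77-fold, adjusted p = 0.17) did not pass, and ACATGT was higher (1.37-fold, adjusted p = 0.019). GAGAGAG was lower with replicate 3 alone (0.78-fold, exact adjusted p = 0.041) and with replicate 2 alone (0.70-fold, adjusted p = 0.0019). Among the 50% of entries with highest signal the CTCF-type motif (1.5-fold, exact adjusted p = 0.74), the M1BP motif (1.69-fold, adjusted p = 0.25) and CACGTG (0.67-fold, adjusted p = 0.19) did not pass, while GAGAGAG (0.51-fold, exact adjusted p = 0.00014) and TCAGTY (0.77-fold, adjusted p = 0.0040) were lower and CACACACA stood at 0.43-fold. With windows of 25 bp to each side the CTCF-type motif (2.75-fold, exact adjusted p = 0.20), CACGTG (0.93-fold, adjusted p = 0.87), CACACACA (0.88-fold, adjusted p = 0.55) and the A tract (1.22-fold, adjusted p = 0.11) did not pass. After merging, the CTCF-type motif (1.71-fold, exact adjusted p = 0.19) and CACGTG (0.72-fold, adjusted p = 0.11) did not pass, and GAGAGAG (0.64-fold, adjusted p = 0.0012) and TCAGTY (0.87-fold, adjusted p = 0.047) were lower. At promoter summits alone the CTCF-type motif (1.88-fold, exact adjusted p = 0.27), CACGTG (0.89-fold, adjusted p = 0.68), CACACACA (0.90-fold, adjusted p = 0.55) and WGATAA (1.13-fold, adjusted p = 0.061) did not pass. Against dinucleotide-shuffled summit windows TAATTA (0.98-fold, exact adjusted p = 0.83), WGATAA (1.01-fold, adjusted p = 0.83) and CACGTG (0.90-fold, adjusted p = 0.74) did not pass, TAACA (0.86-fold, exact adjusted p = 5.2e-07) and ACATGT (0.72-fold, adjusted p = 0.0058) were lower, and CACACACA (4.27-fold, exact adjusted p = 7.5e-22) and GAGAGAG (3.28-fold, adjusted p = 7.0e-15) were higher. TATAAA stood at 1.11-fold in that comparison, and the DREF, CTCF-type and M1BP sites, rare in shuffled sequence, at 12.9-fold, 7-fold and 70-fold. Shuffling breaks up tandem repeats such as CACACACA and GAGAGAG, so their ratios in that comparison do not show an excess at summits.

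Of all 6-mers, 369 were more frequent at summits and 771 less. The highest ratios were for CGATAG (377 against 161 windows, 2.34-fold), TATCGA (518 against 241, 2.15-fold), ATATTA (939 against 462, 2.03-fold), AATAGT (507 windows at summits, 1.98-fold) and TTTAAA (985 against 500, 1.97-fold). Of the 369, 224 held at least 5 A or T bases. Against 5618 pooled entries that did not pass the IDR filter, matched 1 to 1 on promoter class and GC content, 15 6-mers were higher, led by AGCCCT (176 against 99, 1.78-fold, Fisher's exact adjusted p = 0.0063), and 6 were lower, down to 0.53-fold for CCAGGA (63 against 118, adjusted p = 0.019). Of the 17 fixed motifs only CGATA was higher (1.14-fold, Fisher's exact adjusted p = 0.017) and only TCAGTY lower (0.81-fold, adjusted p = 0.0047). In that comparison TAATTA (1.05-fold, exact adjusted p = 0.63), TAACA (1.06-fold, adjusted p = 0.34) and the DREF site (1.19-fold, adjusted p = 0.40) did not pass, and the M1BP site was equal (70 and 70). Background entries that overlap or adjoin IDR peaks were not left out, which could draw ratios toward 1.

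**Figure D4:**
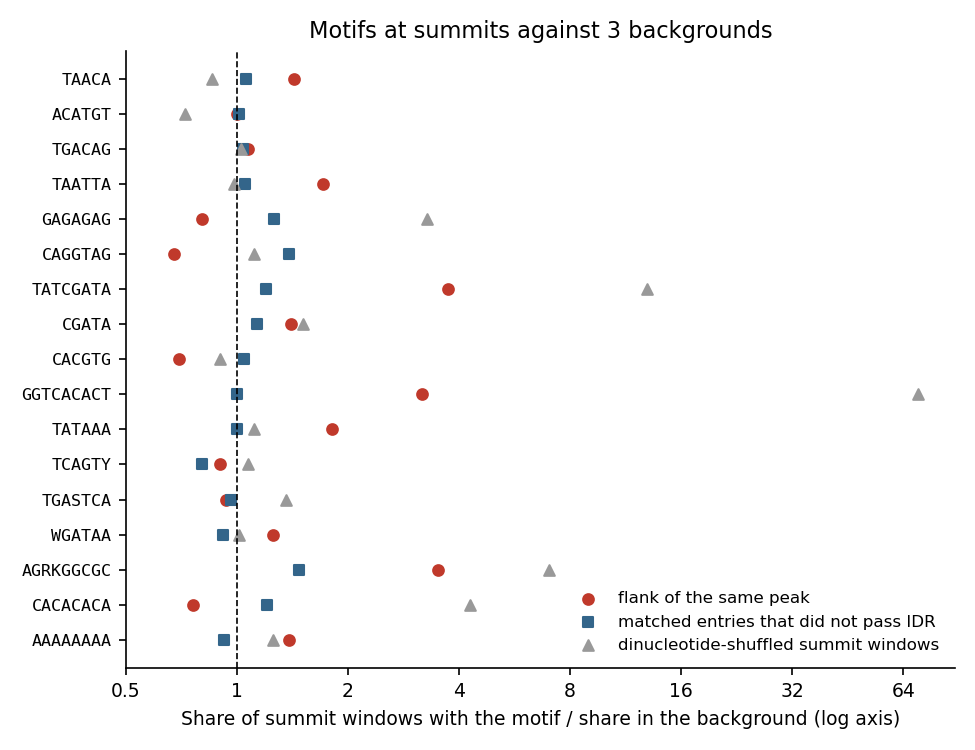
Ratio of the share of summit windows with each of the 17 motifs to its share in flanks of the same peaks (red), in matched entries that did not pass the IDR filter (blue) and in dinucleotide-shuffled summit windows (grey), on a log axis. TAATTA stood at 1.71 against flanks, 1.05 against matched entries and 0.98 against shuffled windows.

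The tagged gene itself lay in a region with 3 peaks. CG11617 (FBgn0031232) spans 2L 204743 to 207297 on the minus strand, with annotated TSSs at 206797 and 207297. An IDR summit at 207367 stood 70 bp upstream of the distal TSS and 39 bp upstream of the TSS of the neighbouring gene Tbc1d15-17 (pooled signal 330, 75.1 in replicate 2 and 270 in replicate 3). Another at 206576 lay 221 bp inside the gene from the proximal TSS (243, 46.5 and 194). The remaining summit, at 203679, was nearest to mRpL10 (596, 198 and 388). Relative to the common shift, replicate 3 was higher by 0.69 and 0.91 on the log2 scale at the summits at 207367 and 206576, against an SD of 0.42 over all entries, and stood at -0.19 at the summit near mRpL10. No test was made for single sites.

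Peak density was similar on the large arms and low on chromosome 4. It was 42.2 per Mb on 2L, 44.8 on 2R, 40.2 on 3L, 43.9 on 3R and 46.4 on X. Chromosome 4 held 21 peaks, or 15.6 per Mb (exact binomial test on arm length, adjusted p = 2.1e-07), and was also lower against pooled entries that did not pass (odds ratio 0.37, Fisher's exact adjusted p = 4.4e-06). The departures of 3L (lower) and X (higher) passed against arm length (exact adjusted p = 0.018 for both) but not against entries that did not pass the IDR filter (adjusted p = 0.13 and 0.58).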

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

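The values in this part were chosen after the lists were examined. On dm3, 4 entries of the authors' IDR set lay on unplaced sequence, above the 3 that a count of 0 allows. They were included in the dm3 counts and signal comparisons, and no test of location, genes or motifs used them. Their pooled signals were 279, 200 and 175 on the sequence U and 145 on Uextra, and every dm6 entry lay on the 6 main arms. The dm6 positions of these sequences were not determined, since no coordinate was converted between builds.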

How the results depend on the processing

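The stratified, promoter-only and shuffled alternatives, and merging for motifs and 6-mers, were chosen after the data were seen. The promoter share, the number of classes that departed from shifted summits, the replicate overlap, the replicate ratio and the signal difference kept their direction and side of the threshold under every alternative run. The promoter share ran from 55.1% (250 bp window) to 74.2% (1000 bp), and from 65.8 to 66.1% with either replicate left out. Replicate overlap fell to 60.9% with a reciprocal overlap of 50% and was 70.7% for summits within 100 bp. Some values moved. The stricter set, with 2865 entries, and the 2502 bound genes of the 50% of entries with highest signal are smaller by construction, and the dm3 set held 7374. The signal correlation was 0.76 for summits within 100 bp, 0.85 among the 50% of entries with highest signal and 0.80 after merging, and the cause was not tested. Against entries that did not pass the IDR filter, 1 arm differed (chromosome 4), 1 fixed motif was higher (CGATA), and 15 6-mers were higher. Only 4 lists differed among genes with a pooled entry, with cytosolic and mitochondrial ribosomal protein genes higher and homeobox and neuronal genes lower. Why the number of lists fell was not tested. Among motifs past the threshold in either of the 2 comparisons, directions turned for 5 against matched entries, to 1.04 for CACGTG, 0.999 for TATAAA, 0.91 for WGATAA, 1.21 for CACACACA and 0.92 for the A tract, none past it there, and for 4 against shuffled windows, to 0.86 for TAACA, 0.98 for TAATTA, 3.28 for GAGAGAG and 4.27 for CACACACA. Shuffling breaks up the tandem repeats GAGAGAG and CACACACA, so their turn against shuffled windows is a property of that background. The cause was weighed only for TAACA, TAATTA and TATAAA, in the last part, and was not tested for the other turns. Over the remaining values for single lists, motifs, classes and arms, 291 were unchanged in call, 33 lost their call and 20 gained one. The tagged gene's locus was not run on dm3, whose gene coordinates were not used here. Without read counts, depth cannot be set against the calls, and with 2 replicates nothing can be tested between samples. No paired analysis was possible because there is 1 group.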

Other observations

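The gene lists and tests in this part were chosen after the data were seen, except the comparisons among genes with a pooled entry and with matched entries, which were planned but read as tests of an explanation only after their results were seen. Glycolysis genes had a promoter peak in 12 of 13 cases (odds ratio 28.1, 4.16 to 1203; Fisher's exact adjusted p = 5.4e-05 over 11 added lists), with pooled signals of 3440 at Gapdh2, 2861 at Hex-A, 2295 at Eno and 928 at Pgk. Aminoacyl-tRNA synthetase genes had 18 of 31 (3.25, 1.5 to 7.21; exact adjusted p = 0.0028; IleRS 650, SerRS 579) and cytosolic chaperonin genes 7 of 8 (16.4; exact adjusted p = 0.0028; CCT8 263, CCT6 261). Cytochrome P450 genes had 13 of 85 (odds ratio 0.42, exact adjusted p = 0.0050; Cyp6u1 896), the Jonah and trypsin proteases 1 of 27 (0.090, exact adjusted p = 0.0028; kappaTry 232) and the Osiris genes 0 of 25 (exact adjusted p = 0.0013). Vacuolar ATPase (12 of 33), Sm and LSm (6 of 11), nucleoporin (8 of 21), mitochondrial import (4 of 15) and glutathione transferase genes (10 of 35) did not pass. The added lists were not run with the alternative windows, peak sets or backgrounds, so how far these calls depend on the setting is unknown.

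Cytosolic ribosomal protein genes that come as lettered pairs did not behave alike, a contrast singled out after its values were seen. Of 8 pairs, 3 had a peak at both members and 5 at 1 member. The bound members were RpL10Ab (396), RpS10b (1450), RpS15Aa (679), RpS19a (831) and RpS28b (842), where RpS10a and RpS15Ab had at most pooled signals of 42.0 and 107, below the IDR set, and RpL10Aa, RpS19b and RpS28a had no pooled entry within 500 bp. RpL34a (932) and RpL34b (1204), RpS14a (731) and RpS14b (850), and RpS5a (818) and RpS5b (175) were bound at both. Copies that are near identical can share reads, and the lists do not show how such reads were placed.

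Among other annotated genes, 301 of 3261 non-coding RNA genes had an IDR summit within 250 bp, against 173 ± 15.1 (SD) in shifted sets (permutation adjusted p = 0.0070). Closeness of these genes to protein-coding promoters was not checked and is not kept by the shifts, so the excess cannot be told apart from promoter peaks. Of 5809 transposable elements, 37 had such a summit, against 351 ± 46.4 (permutation adjusted p = 0.0070), and 390 had any pooled entry. Repeated copies can share reads, and the lists do not show how such reads were placed, so this low count is uncertain. Transfer RNA genes had 12 of 290, against 6.39 in shifted sets, and did not pass (permutation adjusted p = 0.19). Pseudogenes (6 of 268), small nuclear (2 of 32), small nucleolar (11 of 269) and ribosomal RNA genes (0 of 99) did not pass either. The ribosomal RNA genes had 0 with a pooled entry and carry the same limit as the transposable elements.

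The excess of peaks at cytosolic ribosomal protein genes was weighed against 3 technical explanations. Stratifying genes by number of TSSs left an odds ratio of 17.3 (8.39 to 35.8), and stratifying by gene length gave 47.8 (21.1 to 109), so neither property accounts for the excess. Among genes with any pooled entry at a TSS the odds ratio was 13.8 (6.04 to 38.7), which argues against a difference in which promoters could be measured at all. Enrichment that any GFP fusion or any highly active promoter would show stays open, because no control sample was analysed here. No biological explanation was tested, since the design has 1 group.

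The excess of the homeodomain cores TAACA and TAATTA and of TATAAA at summits was weighed against base composition. Against summit windows shuffled to keep dinucleotide counts, TAACA was less frequent (0.86-fold) and TAATTA nearly equal (0.98-fold), so neither exceeded what the composition of the summits gives. TATAAA kept a small excess (1.11-fold, exact adjusted p = 0.0058) that this composition does not account for. Flanks were not shuffled, so how much of the excess over flanks composition would give was not measured. The criterion written before the test, for all 3 motifs together, could not decide, and the reading by motif was chosen afterwards. Against matched entries that did not pass the IDR filter all 3 lay between 0.999 and 1.06, as they would if such sequence is shared by weaker candidate regions. Entries that overlap or adjoin IDR peaks were not left out of that background, so some can come from the same regions, and the comparison cannot tell these apart. No biological explanation was tested.

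The low density on chromosome 4 has 2 technical candidates. Genes are sparser there, at 59.3 per Mb against 105 elsewhere, and 18 of its 80 genes (22.5%) had a promoter peak against 30.0% of others (odds ratio 0.68, 0.38 to 1.16, exact p = 0.18). Gene density alone would give 24.6 peaks per Mb if all peaks followed gene number. That is just above the Poisson interval of 9.64 to 23.8 around the observed 15.6, a comparison chosen after the other. Since 1936 of 5777 summits were not at promoters, how much of the low density sparse genes account for stays open. Poor mapping is not favoured, since 0.99% of entries that did not pass the IDR filter lay on chromosome 4, which makes up 1.01% of the length. Those entries were thus not scarce there despite the fewer genes, though only 36.8% of them in all were promoter summits. No biological explanation was tested.

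A hypothesis was that glycolysis genes as a group are preferred sites of CG11617-GFP enrichment, raised by Gapdh2, Hex-A and Eno near the top of the list. Without these 3 genes, 9 of 10 glycolysis genes had a promoter peak against 29.9% of others (odds ratio 21.1, 2.92 to 925, exact p = 0.00014), so the remaining members show the same excess. The wide interval reflects the 10 genes, and the test used the same peak set that raised the idea.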
